A study of Mus musculus with 16 samples.

How the data were processed

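Total RNA of primary macrophages from 16 samples of Ldlr-deficient mice was extracted with Trizol, converted to labelled cRNA and hybridised to Illumina mouse bead arrays, per the labels' protocols. The values were linear array intensities, deposited by the authors as 1 table with a column per sample. BeadStudio was used, per the submitters' processing notes, which give no version. No further step is named in the sources used here. In the deposited values the sorted intensities of the 16 arrays differed by at most 0.103 in the brighter part and 0.438 in the dimmer part, so the arrays had been made equal in distribution (quantile normalized), with the background left in. No per-sample column was left unused, no pair of columns held identical values, and Spearman correlations were 0.930 to 0.951 within groups and 0.924 to 0.950 between groups. The number of arrays limits the precision. The chip and chip position of each sample, and detection p-values, were not used here, so a chip could not enter as a block.

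Genes were named from the platform annotation, with symbols updated through Entrez identifiers in the RefSeq gene table of GRCm38.p6 (23962 probes matched). Of 25697 probes, 23978 had 1 gene symbol, 0 had several and 1719 had none, and the named probes covered 16593 genes. No build is named with the array values, so the gene table served only for names, for the chromosome and for the distance of genes from Adam17.

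Quantile normalization was applied between arrays and values were taken as log2(value + 16). Groups were genotype by sex as the labels give them (4 groups of 4). limma 3.58.1 in R 4.3.3 was fitted with lmFit and eBayes on the 4 group means, so that all groups shared 1 estimate of the spread. Contrasts were ex/ex against wild type averaged over the sexes, within females, within males, their difference (interaction), and male against female averaged over genotypes. Adjusted p-values are Benjamini-Hochberg values over all 25697 probes, with a threshold of 0.05. For Adam17 an exact two-sided permutation test within sex was added.

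The text names genes by a rule fixed in advance. For the genotype effect it takes the 15 genes with the largest rise and the 15 with the largest fall among probes past the threshold (1 probe per gene, the one with the smaller p). For each within-sex effect and the sex effect it takes the 5 largest in each direction past the threshold, or else the 3 with the smallest p. For the interaction it takes the 3 with the smallest p when none pass, and for each gene list up to 4 members with the smallest genotype p. Adam17 was reported first. Genes of the Adam17 neighbourhood, genes that passed only within a list, Tnf and its receptors, Irf1 in the interaction, and some examples by sex were named outside this rule, after their values were seen.

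The analysis used 35 gene lists with 753 genes, of which 663 were measured, with 1 probe per gene (the highest mean). They cover ADAM17 biology, macrophage function, lipid handling, cell state, sex-linked genes and markers of macrophages and of 9 other cell types. Lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry. Camera asks whether a list moves relative to the other genes. Fry asks whether its genes move, on balance, in 1 direction, and does not compare them with other genes. Adjusted p-values of lists are Benjamini-Hochberg values over the 35 lists. Member counts are given over all probes and adjusted over the list alone. Female and male fold changes were compared by Pearson correlation across probes. Probes within 20 Mb of Adam17 were compared with all others by a two-sided Fisher's exact test, with Wilson 95% intervals for shares. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

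The model was tested on simulated data with 200 changed probes among 25697. For the genotype contrast it recovered 81.5%, 98.6% and 100% of changes of 0.25, 0.5 and 1 log2 units, with 8 false calls among 197. For females the shares were 70.8%, 93.0% and 100%, for males 76.9%, 95.7% and 98.5%, for the interaction 67.7%, 86.5% and 100%, and for sex 89.5%, 98.6% and 100%. For lists, over 16593 genes, a list shifted by 0.2 gave an adjusted p of 2.36e-43, and 0 of the 27 lists that shared no gene with it passed in camera. The simulated probes and genes were drawn independently, so these values do not measure false calls that come from correlated genes. In the real data, other splits of the samples within sex gave a median of 2 lists past the camera threshold by genotype, and up to 14.

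The groups, contrasts, gene lists, naming rule and most alternatives were chosen before the data were examined. Those alternatives were no further normalization, median centring, offsets of 1 and 50, dim probes left out (below the 50th percentile), eBayes with intensity trend and robust prior (with statmod 1.5.0), array weights, the replicate number as a block, the mean of a gene's probes, no sex term, treat against a fold of 1.2, fits within 1 sex or 1 genotype, windows of 10 and 40 Mb or the 100 and 200 smallest p for the neighbourhood, and each sample left out in turn. Alternatives added after the data were examined left out wild-type male 2 and ex/ex male 4 together (the lowest array weights, 0.61 and 0.56, against 0.91 to 1.36 in the others), subtracted the lowest intensity as background, or left out genes within 20 Mb of Adam17.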

Results

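Gene expression was measured with Illumina bead arrays in 16 samples of primary mouse macrophages. All animals came from an Ldlr-deficient line on a C57BL/6 background, in which loss of the LDL receptor raises plasma cholesterol. Per the labels, 8 samples were Adam17 wild type (wt/wt) and 8 were homozygous for the hypomorphic Adam17 ex allele (ex/ex). Each genotype held 4 female and 4 male samples, which gave 4 groups of 4. Adam17 encodes a membrane protease that sheds TNF, both TNF receptors and many other surface proteins. The series title places the comparison in the context of atherosclerosis and TNF receptor 2 signalling. The design text counts 8 mice per genotype, but no label ties a sample to its animal, so p-values measure the spread between these samples. The number of arrays limits the precision of a value. Each array gave 25697 probe intensities. Fold changes are on the log2(value + 16) scale, which understates the change of dim genes.

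Adam17 itself was lower in every ex/ex sample. Its single probe (ILMN_2594718) had a mean intensity of 1455 ± 99.7 (SD, n = 8) in wild-type and 329 ± 26.1 (SD, n = 8) in ex/ex macrophages, a fall by 2.09 ± 0.05 (SE) on the log2 scale. The adjusted p of limma was 8.46e-12, and the exact two-sided permutation test within sex gave p = 0.000408, the smallest that its 4900 relabelings allow. The difference was -2.07 in females and -2.11 in males, and the lowest wild-type sample (1222) lay above the highest ex/ex sample (360.0). The position of the probe relative to the exon inserted in the ex allele is not known here.

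**Figure D1:**
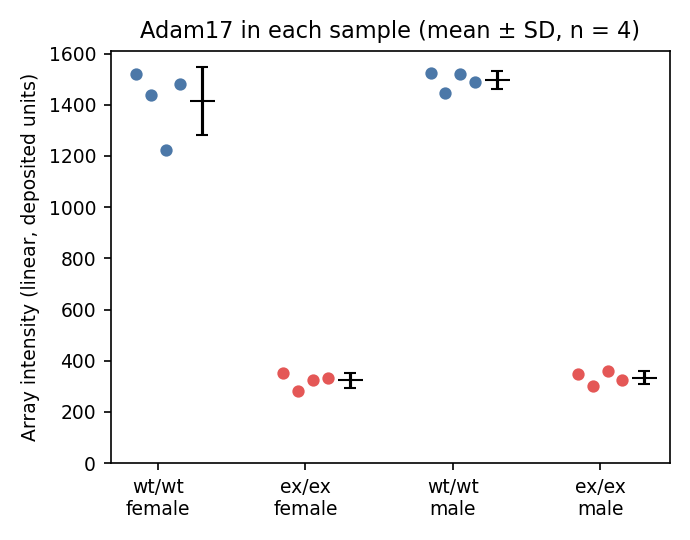
Adam17 probe intensity (linear units) in each sample of the 4 groups, with mean and SD beside the points (n = 4). All 8 ex/ex samples lie at or below 360.0 and all 8 wild-type samples at or above 1222.

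The comparison of ex/ex with wild-type macrophages, averaged over the sexes, asks which other transcripts differ between the genotypes. Podoplanin (Pdpn), a mucin-like membrane glycoprotein, rose by 0.85 ± 0.13 log2 units (SE, n = 8 per genotype). Its mean intensity went from 1438 to 2151 in females and from 933 to 2006 in males. Caveolin-1 (Cav1), the coat protein of caveolae, rose by 0.81 ± 0.12, syndecan-1 (Sdc1), a heparan sulfate proteoglycan and ADAM17 substrate, by 0.60 ± 0.12, and protocadherin-7 (Pcdh7) by 0.60 ± 0.08. The lipid phosphate phosphatase Plpp3 rose by 0.85 ± 0.12 and the sphingosine kinase Sphk1 by 0.64, both enzymes of bioactive lysolipids. Il1rn, which encodes the interleukin-1 receptor antagonist, rose by 0.67 ± 0.15.

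The other named rises were Adi1 (1.23 ± 0.14), an enzyme of the methionine salvage pathway, Bcar3 (0.85 ± 0.16), Plk2 (0.72 ± 0.12), the transcriptional inhibitor Id2 (0.69 ± 0.04), Neo1 (0.68), Pxdc1 (0.65), Rgs1 (0.57) and Phldb1 (0.57). After Adam17, the largest falls were Odc1 (-1.003 ± 0.204), the rate-limiting enzyme of polyamine synthesis, the p53 target Sesn1 (-0.83 ± 0.15) and Twistnb (-0.82 ± 0.10), a subunit of RNA polymerase I. The transporter Slco2b1 fell by 0.74 ± 0.09, the interferon-response transcription factor Irf1 by 0.68 ± 0.13 and the oxysterol receptor Gpr183 by 0.57. The aryl hydrocarbon receptor repressor Ahrr (-0.50 ± 0.06), Fchsd2 (-0.48), the adaptor Gab3 (-0.45), the sialyltransferase St8sia4 (-0.44), Nfatc1 (-0.44), Ints6l (-0.44), Snx24 (-0.43) and Lyzl4 (-0.43) followed. Each of these 30 genes lay on the stated side of the wild-type mean of its sex in 8 of 8 ex/ex samples, with limma adjusted p from 8.46e-12 (Adam17) to 0.0479 (Snx24). For Il1rn, Sdc1, Sphk1, Irf1 and Nfatc1, among others, some probes of the gene did not pass: 1 of 3 passed for Il1rn, Sdc1 and Sphk1, 2 of 5 for Irf1 and 2 of 6 for Nfatc1.

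With limma and Benjamini-Hochberg adjustment, 360 of the 25697 probes passed, 202 higher and 158 lower in ex/ex, and these named 300 genes. At unadjusted p below 0.05 there were 3065, against 1285 that chance alone would give. Most differences were small, since 25 of the 360 exceeded 1.5-fold and 3 exceeded 2-fold. These 3 were the probes of Adam17, Adi1 and Odc1, and the last 2 genes lie within 20 Mb of Adam17. The genotype count fell to 185 without ex/ex female 4, 209 without wild-type female 1 and 221 without ex/ex female 3, to 82 without a sex term, and to 4 when tested against a fold change of 1.2. All 4 of these probes lay within 20 Mb of Adam17. Of the 16 fits that each left out 1 sample, 14 lost the call of Snx24, 13 that of Neo1, 12 those of Il1rn and Pxdc1, 11 that of Lyzl4, 9 that of Sphk1, 7 that of Sdc1 and 6 that of Odc1.

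**Figure D2:**
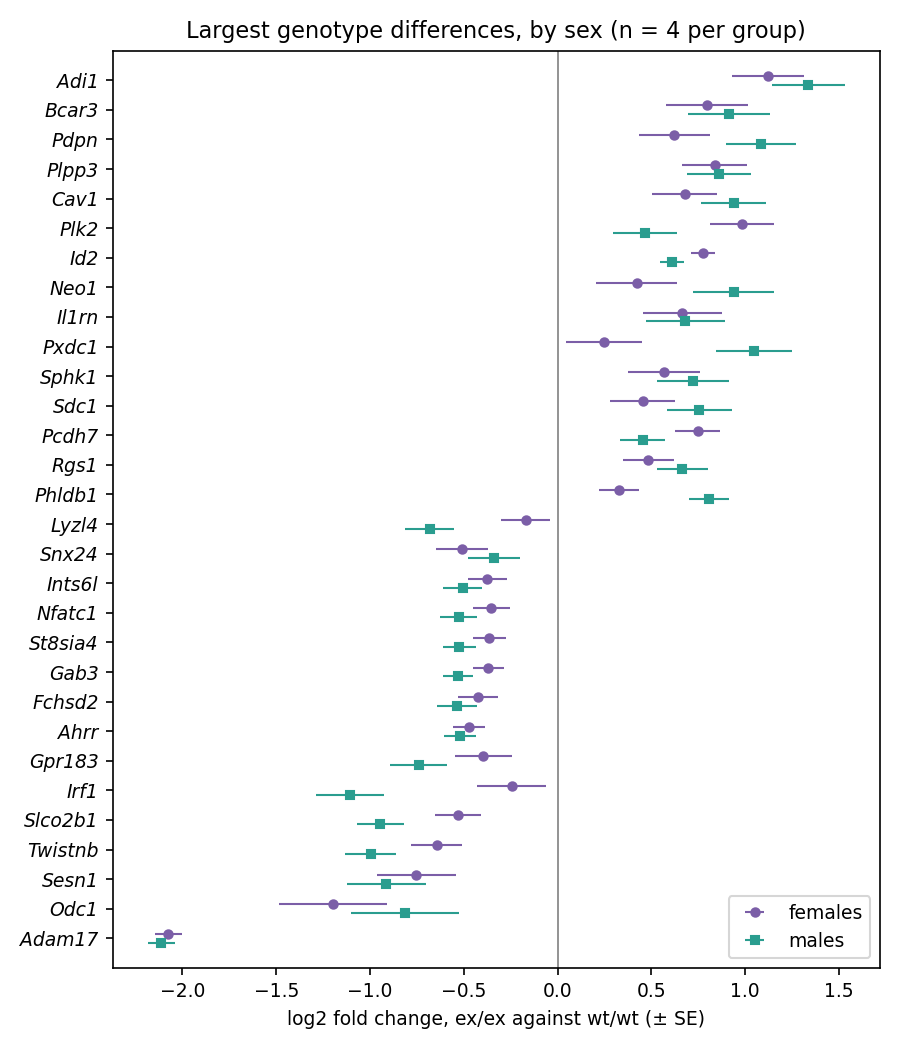
Log2 fold change of ex/ex against wild type in females and in males (points, ± SE, n = 4 per group) for the 30 genes with the largest rises and falls. All 30 differences have the same sign in both sexes, which their choice by the effect averaged over the sexes favours.

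Genes coding for ADAM17 substrates lay slightly higher in ex/ex as a group in camera. Chance cannot be excluded for the 6 lists that passed by genotype, since 17 of 100 splits of the samples gave as many. Of 33 substrates measured, 23 were higher and 10 lower in ex/ex. The 1 that passed over all probes, Sdc1, lies within 20 Mb of Adam17. When adjusted over the list alone, 6 passed (Sdc1, Cd44, Cx3cl1, Hbegf, Alcam and Csf1, all higher). Camera gave an adjusted p of 0.00773 for the list, and the adjusted p was 0.0474 with an estimated correlation. Over all probes Cd44 (0.26, adjusted p = 0.0526, 8 of 8 samples) and the EGF receptor ligand Hbegf (0.35, adjusted p = 0.139, 8 of 8 samples) did not pass. The shift was small, with a median of 0.03 log2 units, and without wild-type male 3 its adjusted p was 0.109. Of 17 ADAM proteases and regulators of ADAM17, only Adam17 passed over all probes, 2 were higher and 1 lower when adjusted over the list alone, and the list did not stand apart (camera adjusted p = 0.956). Its median was 0.01 and its mean -0.10, the latter drawn down by Adam17. Adam8 (0.25, adjusted p = 0.0510) was higher in 8 of 8 ex/ex samples without passing.

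Among 25 leukocyte adhesion genes and integrins, 16 were higher and 9 lower. Of these the integrin Itgav rose by 0.38 ± 0.05 (adjusted p = 0.00345, 8 of 8 samples), and 5 passed when adjusted over the list alone (Itgav, Cd44, Itga5, Alcam and Itgb1, all higher). Cd44 and Alcam are also among the ADAM17 substrates above, so these lists overlap. The adhesion list passed in camera (adjusted p = 0.0329) but not with an estimated correlation (adjusted p = 0.111). Without wild-type male 3 its adjusted p was 0.109. Among 24 apoptosis and survival genes, 19 were lower, and 3 fell, both over all probes and adjusted over the list alone. These included Apaf1, the scaffold of the apoptosome (-0.26, adjusted p = 0.00351, 8 of 8 samples), and the BH3-only gene Bbc3 (-0.39, adjusted p = 0.0222, 8 of 8 samples). Birc2, an inhibitor of apoptosis, was the other (-0.17, adjusted p = 0.0426, 8 of 8 samples), so genes for and against cell death were both lower. Camera gave an adjusted p of 0.00204 for this list, and 0.0378 was the adjusted p with an estimated correlation. Without ex/ex female 4 the adjusted p of Bbc3 was 0.0552, and the call of Birc2 was lost in 13 of the 16 fits without 1 sample.

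Cell cycle, cholesterol biosynthesis and interferon-stimulated genes lay lower in ex/ex without any single member passing. Of 40 cell cycle genes, 35 were lower (median -0.18, camera adjusted p = 1.77e-07), for example Aurka (-0.37, adjusted p = 0.207, 7 of 8 samples) and Cdk2 (-0.30, adjusted p = 0.206, 8 of 8 samples). Of 18 genes of cholesterol biosynthesis, 15 were lower (median -0.15, camera adjusted p = 0.00731), among them Mvd (-0.34, 7 of 8 samples) and Fdps (-0.44, 7 of 8 samples). Of 38 interferon-stimulated genes, 33 were lower (median -0.05, camera adjusted p = 0.00773), such as Gbp3 (-0.22, 7 of 8 samples) and Ifi47 (-0.28, 7 of 8 samples). The limma count of passing members was 0 in each of these 3 lists, also when adjusted over the list alone, and at unadjusted p below 0.05 it was 13 (12 of them lower), 3 and 3. None of the 3 calls held with an estimated correlation, which gave adjusted p = 0.746 for each, and none held in fry. The calls for cholesterol biosynthesis and interferon-stimulated genes were also lost without single samples, with adjusted p up to 0.0683 (without ex/ex female 3) and 0.368 (without ex/ex male 3). Ex/ex male 4 lay below all other males in the first principal component (-2.88, against 10.33 to 22.87). The males differed from the females in the cell cycle list.

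The TNF pathway showed no joint shift. Of 28 measured components of TNF receptor signalling, 2 fell: the kinase Mapk14 (-0.27, adjusted p = 0.00796, 8 of 8 samples) and Birc2. When adjusted over the list alone, 4 were higher and 2 lower, and camera gave an adjusted p of 0.404. Tnfrsf1b, which encodes TNF receptor 2 and was picked out because the series title names it, differed by 0.02 ± 0.05 (adjusted p = 0.930). Its mean log2 values of 6.95 to 6.99 were near the background of the array. Tnfrsf1a differed by 0.04 (adjusted p = 0.864) and Tnf by -0.13 ± 0.12 (adjusted p = 0.771), both picked out for the same reason. Among 40 NF-kB target genes Il1rn rose and Junb fell (-0.33 ± 0.04, adjusted p = 0.00285, 8 of 8 samples). When adjusted over the list alone 4 were higher and 5 lower, and Cxcl10 (-0.23, adjusted p = 0.0572) did not pass over all probes. The list as a whole gave a camera adjusted p of 0.956.

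Macrophage polarisation and lipid handling genes gave few calls. Of 22 inflammatory (M1) genes only Irf1 fell, and 2 were lower when adjusted over the list alone (camera adjusted p = 0.655). Of 26 alternative (M2) genes none passed in limma, although 7 had an unadjusted p below 0.05 (2 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.610). Pparg, the lipid-sensing nuclear receptor (0.50, adjusted p = 0.0561), and the mannose receptor Mrc1 (-0.34, adjusted p = 0.0702) lay on 1 side in 8 of 8 samples. None of 21 cholesterol efflux and LXR target genes (camera adjusted p = 0.779) and none of 24 scavenger receptor and lipid-loading genes (0.772) passed in limma, with 3 and 2 at unadjusted p below 0.05 and 0 in either list when adjusted over the list alone. Single members rose in the chemokine list (Cxcl14, 0.56, adjusted p = 0.0103, 8 of 8 samples) and in the matrix list (Mmp14, 0.42, adjusted p = 0.0271, 8 of 8 samples), and the elastase gene Mmp12 did not pass (0.62, adjusted p = 0.108, 7 of 8 samples). Without ex/ex female 4 the adjusted p of Mmp14 was 0.0643. Nqo1, a target of NRF2, fell (-0.20, adjusted p = 0.0103, 8 of 8 samples), as did the heat shock gene Dnajb1 (-0.26, adjusted p = 0.0159, 8 of 8 samples). Adjusted over the list alone, the counts higher and lower were 2 and 2 for chemokines, 4 and 0 for matrix genes, 4 and 1 for NRF2 targets, and 4 and 5 for immediate early and heat shock genes. In all, 6 of 35 lists passed in camera by genotype, 2 with an estimated correlation (ADAM17 substrates, and apoptosis and survival) and 6 in fry. The calls in fry left out cell cycle, cholesterol biosynthesis and interferon-stimulated genes, so the 6 in fry are not the 6 in camera. Markers of 9 other cell types held no passing member in limma (10 of their members had an unadjusted p below 0.05) and had medians of at most 0.02 log2 units in size (smallest camera adjusted p = 0.443), although most of these probes lay near the background of the array.

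Genes near Adam17 were over-represented among the genotype calls. Distances between genes were taken from the RefSeq annotation of GRCm38.p6, since no build is named with the array values. Within 20 Mb of Adam17 on chromosome 12, 18 of 173 probes passed (10.4%), against 323 of 23789 elsewhere (1.36%). The odds ratio was 8.43 (95% interval 4.81 to 14.0, two-sided Fisher's exact test p = 5.99e-11), and 7.97 without Adam17 (p = 4.41e-10). Probes of the same gene are not independent. With 1 probe per gene (the highest mean), 12 of 116 in the window passed, against 253 of 16466 elsewhere. The odds ratio was then 7.39 (two-sided Fisher's exact test p = 3.41e-07), and 6.78 without Adam17 (p = 2.23e-06). The 18 probes named 12 genes. Sdc1, Id2, Trappc12 (0.49), Adi1 and Bcap29 (0.31) rose, and Adam17, the lipin gene Lpin1 (-0.28), Pqlc3 (-0.35), Odc1, Sh3yl1 (-0.10), Twistnb and Zfp277 (-0.19) fell. All 18 probes had the same sign in both sexes, which their choice by the effect averaged over the sexes favours. Thus Adi1, Id2, Sdc1, Odc1 and Twistnb, named above among the largest differences, are neighbours of the targeted gene. A refit without the probes of this window called 320 probes, all of them among the 360. Since only 18 of the 360 lay in the window, the refit also lost calls outside it, among them that of Snx24.

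**Figure D3:**
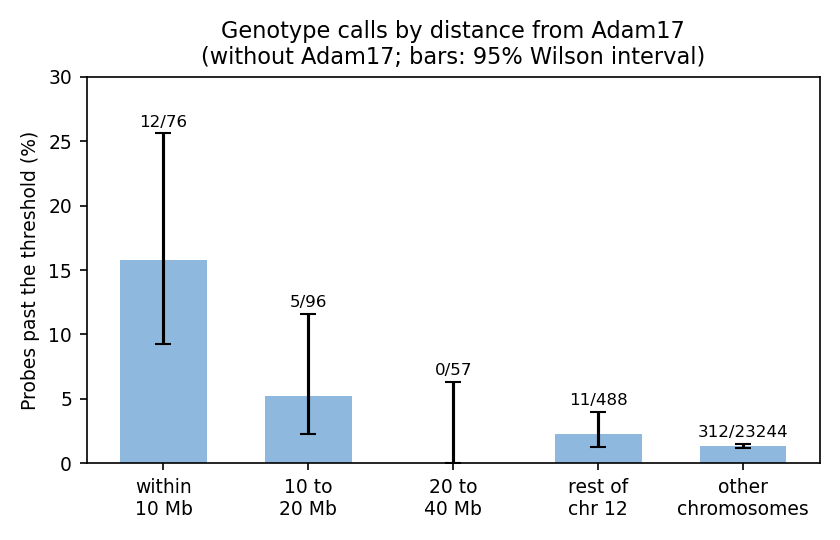
Percent of probes past the genotype threshold by distance from Adam17, without the Adam17 probe (bars, 95% Wilson interval; called and tested probes above). The share is 15.8% within 10 Mb, 5.21% from 10 to 20 Mb and 1.34% on other chromosomes.

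Within females the comparison called Adam17, Id2 and Slc2a1. Id2 rose by 0.77 and 0.73 on its 2 probes, and Slc2a1, which encodes the glucose transporter GLUT1, rose by 0.34 (adjusted p = 0.0435), each in 4 of 4 ex/ex samples. The call of Slc2a1 was lost in 10 of the 16 fits without 1 sample, with an adjusted p of up to 0.160 (without wild-type female 1). With limma, 4 probes passed in females, 3 higher and 1 lower (2067 at unadjusted p below 0.05). This count depended on single samples: it was 46 without wild-type male 2, 37 without ex/ex male 4, 21 without ex/ex female 1, 16 without wild-type female 4, and 8 without ex/ex female 2 or without ex/ex male 2. Male samples enter it because all groups share 1 estimate of the spread.

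Within males the largest rises were Adi1 (1.34), Pdpn (1.08), Pxdc1 (1.05), Cav1 (0.94) and Plpp3 (0.86). The largest falls after Adam17 were Irf1 (-1.11), Twistnb (-0.997), Slco2b1 (-0.94) and Lyzl4 (-0.68), each in 4 of 4 ex/ex samples, with limma adjusted p from 9.95e-10 (Adam17) to 0.0491 (Plpp3). Of the 16 fits without 1 sample, 14 lost the call of Plpp3, 13 those of Pxdc1 and Lyzl4, 8 that of Cav1, 6 that of Pdpn and 3 that of Irf1. All 6 of these calls were also lost with male samples only. In all 92 probes passed, 47 higher and 45 lower (2832 at unadjusted p below 0.05). The count moved to 206 without ex/ex male 1 and 142 without wild-type male 2. It moved to 37, 26 and 43 without wild-type male 1, 3 and 4, and to 38, 31 and 26 without ex/ex male 2, 3 and 4.

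The genotype difference ran in the same direction in both sexes for most of these probes. Of the 92 called in males, 79 had the same sign in females, 52 had an unadjusted p below 0.05 there, and 4 were called in both (Adam17, both probes of Id2, and Slc2a1). Across all probes, which are not independent replicates, the female and male fold changes correlated with r = 0.432, and 54.6% had the same sign. Among the brighter probes, those above the median, r was 0.449 and 59.0% had the same sign. The 2 comparisons share no samples.

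Whether the genotype difference itself depended on sex was tested as an interaction. The genes with the smallest p were Lpar6, a lysophosphatidic acid receptor (-0.49 in females and 0.76 in males, interaction 1.25, adjusted p = 0.114), the cyclin Ccnf (interaction -0.19, adjusted p = 0.382) and Eif4enif1 (-0.37, adjusted p = 0.382). None passed. Irf1, which fell by 1.11 in males and differed by -0.24 in females, had an interaction of -0.86 with adjusted p = 0.764. The limma count was 0 of 25697 probes, with 1594 at unadjusted p below 0.05, and 1 probe passed with an intensity-trended, robust prior. Without wild-type male 2 it was 4, and without ex/ex male 4 it was 2.

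Some lists, each fixed beforehand, differed between the sexes in camera. Interferon-stimulated genes had a median of -0.16 in females and -0.02 in males, with 33 of 38 interactions above 0 (adjusted p = 0.00174, and adjusted p = 0.725 with an estimated correlation). MHC class II genes had medians of -0.12 and 0.16, with 13 of 15 interactions above 0 (adjusted p = 0.00174, and 0.365 as adjusted p with an estimated correlation). In H2-Aa the difference was -0.31 in females and 0.16 in males. Cell cycle genes (median interaction -0.17, adjusted p = 0.00295), oxidative phosphorylation genes (-0.06, 35 of 46 below 0, adjusted p = 0.00174) and ADAM proteases and regulators (adjusted p = 0.0389) also passed. With an estimated correlation these 3 lost their calls, with adjusted p = 0.725, 0.682 and 0.365. Without ex/ex male 4 the calls of cell cycle (adjusted p = 0.485) and oxidative phosphorylation genes (0.0685) were lost, and without ex/ex male 2 that of interferon-stimulated genes (0.460). The call of the ADAM list was lost in 9 of the 16 fits without 1 sample. In fry none of the 35 lists passed for the interaction, and 3 had an unadjusted p below 0.05. The camera count moved from 5 to 8 without wild-type male 2, to 2 without ex/ex male 4, and to 3 without ex/ex female 1, ex/ex female 4 or wild-type female 2.

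In females alone 2 lists passed in camera, interferon-stimulated genes (34 of 38 lower, adjusted p = 1.53e-05) and apoptosis and survival (adjusted p = 0.0435). Both calls were lost with an estimated correlation, at adjusted p = 0.811 and 0.2004. That count was 5 without wild-type female 2, 4 without ex/ex female 1 or wild-type female 3, and 1 without wild-type female 4, ex/ex female 4, wild-type male 2 or wild-type male 3. In males 8 lists passed. ADAM17 substrates (adjusted p = 0.00313), matrix genes (0.0482), MHC class II (0.0457) and lysosome genes (0.00961) were higher. Cholesterol biosynthesis (0.0212), cell cycle (9.28e-09), apoptosis and survival (0.0106) and oxidative phosphorylation (0.00219) were lower. With an estimated correlation only the substrates passed (adjusted p = 0.0442), and the other 7 had adjusted p of 0.0741 or more. The male count was 3 without wild-type male 3 or without ex/ex male 4, and the genotype count over both sexes was 2 without wild-type male 3.

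Male and female macrophages differed far more than the genotypes did. Cell cycle genes were higher in males throughout: all 40 lay above 0 and 35 passed, both over all probes and adjusted over the list alone (median 0.90, camera adjusted p = 7.95e-30, and adjusted p = 0.126 with an estimated correlation). Prc1, which bundles spindle microtubules, rose by 2.50 ± 0.29 (adjusted p = 3.00e-05), Nusap1 by 2.29, Plk1 by 2.04 and Top2a by 1.997, each with no overlap between the 8 male and 8 female samples. The histone genes H2ac24 (2.70), H2ac10 (2.51) and H2ac22 (2.39) were also higher, but their near-identical copies make the assignment of these probes uncertain. Of 15 MHC class II genes 7 were lower and 2 higher in males over all probes, 6 did not pass, and the counts were 8 and 2 adjusted over the list alone (camera adjusted p = 0.0179, and 0.287 as adjusted p with an estimated correlation). Cd74, the invariant chain, fell by 1.48 ± 0.20 (adjusted p = 8.22e-05), H2-Ab1 by 1.52, H2-Eb1 by 1.36 and H2-Aa by 1.26 from females to males, each in 8 of 8 male samples.

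From females to males Gdf3 fell by 1.69 ± 0.20 (adjusted p = 2.84e-05), Apoe, the apolipoprotein of macrophage cholesterol efflux, by 1.61 ± 0.28 (7.51e-04), the cytokine Il1b by 1.58 ± 0.28 (7.86e-04) and Nfil3 by 1.46 ± 0.20 (1.15e-04), each in 8 of 8 male samples. With wild-type samples only the call of Apoe was lost (adjusted p = 0.0905). Of 33 lysosome and phagocytosis genes 13 fell over all probes, such as the bridging protein Mfge8 (-0.66), and 15 were lower and 1 higher adjusted over the list alone (camera adjusted p = 1.42e-04, and 0.287 as adjusted p with an estimated correlation). Of 24 immediate early and heat shock genes 12 fell over all probes, such as Fosb (-1.31) and Egr2 (-0.88), and 14 adjusted over the list alone (camera adjusted p = 1.91e-04, and 0.198 as adjusted p with an estimated correlation). Of 46 oxidative phosphorylation genes 21 rose and 2 fell, with Cox6a1 (0.33) and Ndufs8 (0.30) among the rises, and 24 were higher and 4 lower adjusted over the list alone (camera adjusted p = 2.37e-05, and 0.287 as adjusted p with an estimated correlation). The sex-linked genes followed the labels in every sample. Eif2s3y (3.58 ± 0.05, adjusted p = 7.00e-16) and Kdm5d (1.27) on the Y chromosome were higher in males, and Xist (-0.60) and the escape gene Kdm6a (-0.61) were lower, with no overlap between the sexes. The Y-linked list passed in camera (adjusted p = 2.37e-05) and with an estimated correlation (0.0135), and the X list passed only in the former (0.0173, and adjusted p = 0.126 with an estimated correlation).

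In total 5316 probes (20.7%) passed in limma for sex, 2534 higher and 2782 lower in males, and 420 of them exceeded 1.5-fold. Of the 35 lists 7 passed by sex in camera, 1 with an estimated correlation and 14 in fry, which does not compare them with other genes. The first principal component, with 59.5% of the variance, parted the sexes, and the second, with 8%, parted the genotypes. Ex/ex male 4 lay at -2.88 on the first, between the other males (10.33 to 22.87) and the females (-7.97 to -19.77). No label gives the array or preparation batch of a sample, so a batch that followed sex could not be examined within itself.

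**Figure D4:**
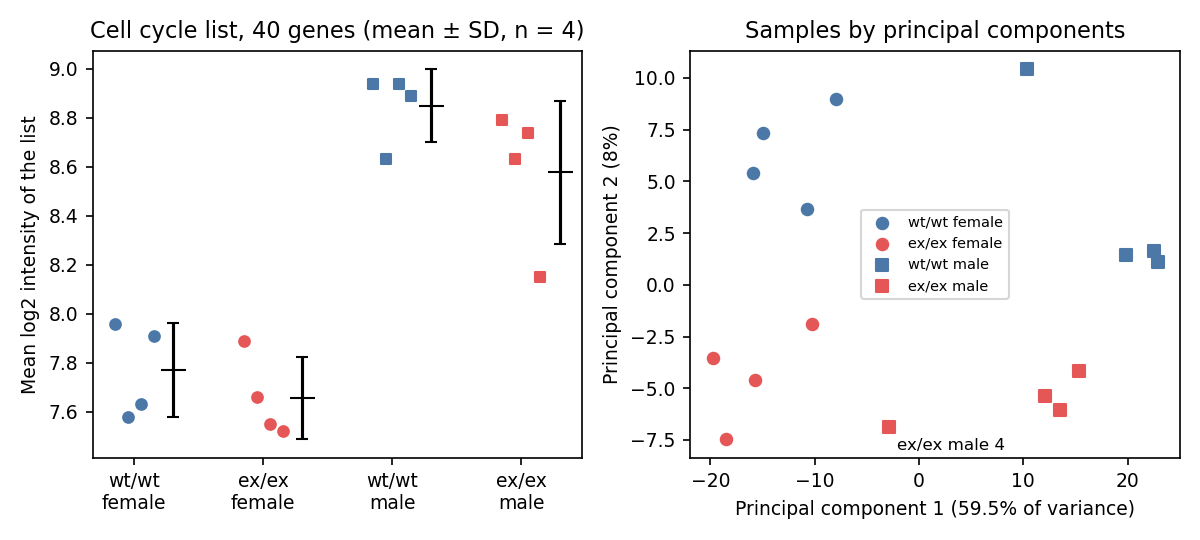
Mean log2 intensity of the 40 cell cycle genes in each sample (left, with mean and SD, n = 4 per group) and the first 2 principal components (right, 1 point per sample). All 8 male samples lie above all 8 female samples in the cell cycle mean, and ex/ex male 4 lies at -2.88 on the first component.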

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

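The test of the genotype label of ex/ex male 4 was chosen only after the result was seen. Of 468 groups of 4 log2 values examined, 33 held 1 sample far from the other 3, against 23.4 that chance would give, since chance marks about 1 in 20 groups. Wild-type male 2 and ex/ex male 4 account for 7 each and wild-type female 1 for 5.

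Wild-type male 2 lay above the other 3 wild-type males for Odc1 (11.98, others 11.37 to 11.47) and Sesn1 (10.57, others 10.17 to 10.22). It lay below them for Ints6l (9.46), H2ac10 (10.45, others 11.18 to 11.33), Cx3cr1 (7.46), Bcap29 (9.88) and the mean of the cell cycle list (8.63, others 8.89 to 8.94). Wild-type female 1 was high for Ccnf (6.74), Cx3cl1 (7.01) and Cx3cr1 (7.85, others 7.05 to 7.09), and low for Sphk1 (7.80) and Fabp5 (8.88). Wild-type male 1 was low for Cav1 (8.83, others 9.03 to 9.05) and Trappc12 (6.75), and wild-type female 4 high for Trappc12 (7.21) and Scd2 (7.56). Ex/ex male 2 was high for Odc1 (11.56, others 10.42 to 10.53) and Apaf1 (9.61), and ex/ex female 4 was low for Apaf1 (9.11). The remaining marked values were Ccl12 in ex/ex female 1 (7.68), Dnajb1 in wild-type female 3 (10.21), Tnf (10.21) and Tnfrsf1a (7.37) in wild-type female 2, Tnfrsf1b (7.02) and Plin2 (9.13) in ex/ex male 1, and Cyp27a1 in ex/ex female 3 (9.86).

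Ex/ex male 4 was high for Plk2 (8.77, others 8.20 to 8.27), Hbegf (7.77, others 7.07 to 7.13) and Ccl3 (9.55), and low for Plk1 (8.39, others 9.43 to 9.56), Fdps (10.42, others 11.40 to 11.44), Ccnf (6.76) and Bcap29 (10.11), besides its place between the sexes on the first principal component. A wrong sex label or admixed female RNA was argued against by Eif2s3y, which lay 0.0565 log2 units above the mean of the other 7 males, and by Xist (6.79, within the 6.75 to 6.86 of the other males and below the 7.26 to 7.60 of the females). A wrong genotype label was argued against by its Adam17 intensity of 327, within the 283 to 360.0 of the other ex/ex samples. A difference in how this sample was prepared, or in how many of its cells were dividing, stays open and was not tested.

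The interaction between genotype and sex passed in camera for 5 lists: ADAM proteases and regulators (adjusted p = 0.0389), interferon-stimulated genes (0.00174), cell cycle (0.00295), MHC class II (0.00174) and oxidative phosphorylation (0.00174). With an estimated correlation 0 of these lists passed (adjusted p from 0.365 to 0.725), and 0 in fry. Chance cannot be excluded for this count. Of 100 splits of the samples, 25 gave 5 or more such lists, the real split included, and the highest other count was 10.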

How the results depend on the processing

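No recomputed value past its threshold changed sign under any of the 33 settings tried. Of the 40 genes named by the rule and past the genotype threshold 29 kept their call in all 16 fits that each left out 1 sample. With treat 37 of these 40 lost it. Leaving aside the fits without 1 sample, 14 kept it in all settings other than treat. The numbers were not taken to pair samples: of 16 same-numbered pairs 7 correlated above 0.1 (-0.24 to 0.33), and own numbers correlated best in 6 of 16. With the block the counts were 419 for genotype, 56 in females, 92 in males (48 of them the same probes), 1 for the interaction and 5069 for sex. It lost the genotype calls of Neo1, Lyzl4 and Bbc3 (37 of the 40 kept) and the male calls of Plpp3, Slco2b1 and Lyzl4. With the block 7 lists passed by genotype, 5 in females, 8 in males and 5 for the interaction, Adam17 stayed at -2.09, the agreement of the sexes at 0.432, and the neighbourhood odds ratio was 7.21. The genotype count of 360 was 82 without a sex term and 4 with treat, the latter by its stricter bound. The female count of 4 was 18 with an offset of 1 (61.1% higher, against 75% for the reported count), 33 with probes above the median, 67 with trend and robust prior, 67 with array weights, 15 with the mean of a gene's probes and 16 with female samples only. The male count of 92 was 184, 220 and 56 with probes above the median, trend and robust prior, and array weights, and 22 with male samples only. The interaction count of 0 was 1 with probes above the median and 1 with trend and robust prior. The sex count of 5316 was 3053 with wild-type samples only, which holds fewer samples. With an estimated correlation 2 lists passed by genotype, 0 in females (3 at unadjusted p below 0.05), 1 in males and 0 for the interaction (3 at unadjusted p below 0.05). Fry gave 5 lists in males and 0 for the interaction, and lists above the median gave 1 in females. Alternatives chosen after seeing the data moved further counts. With both low-weight males left out, females gave 91, males 83 (31.3% higher, against 51.1%), the interaction 8, lists in females 5 and lists by interaction 8. With background subtracted, females gave 63, males 204 (61.8% higher), the interaction 1 and lists in females 4. Except where named, the cause was not tested.

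Leaving out 1 sample at a time gave 185 (ex/ex female 4) to 407 probes by genotype, 3 to 46 (wild-type male 2) in females, 26 (wild-type male 3 and ex/ex male 4) to 206 (ex/ex male 1) in males, 0 to 4 (wild-type male 2) for the interaction and 4802 to 5663 by sex. Lists ranged from 2 to 9 by genotype, 1 to 5 in females, 3 to 8 in males and 2 to 8 for the interaction. Adam17 ranged from -2.13 to -2.06, the agreement from 0.334 to 0.487 and the odds ratio from 6.48 to 11.5. Other samples that moved a count by over 1.5 times stand beside that count above, and the cause was not tested. The neighbourhood odds ratio ran from 6.15 to 23.0 over 31 settings (largest Fisher's exact p = 2.29e-07). Treat gave no odds ratio, since all 4 of its calls lay in the window. Array values limit dim genes: the lowest intensity was 73.7 and the median 92.4 with background left in, and subtracting it moved Adam17 to -2.37 and the genotype count to 507.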

Other observations

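The tests of probe mismatch, linked DNA and response near Adam17, and those of a batch following sex and of other cell types, were chosen only after the result was seen. Chemokine and lipid genes split by sex in both directions. Of 33 chemokines and their receptors 6 were higher and 6 lower in males. The monocyte attractant Ccl12 rose by 1.55 ± 0.15 (SE, n = 8 per sex, adjusted p = 7.61e-06, 8 of 8 male samples) and the fractalkine receptor Cx3cr1 by 0.94, while Ccl4 (-1.02), Ccl3 (-0.98) and Ccl5 (-0.71) fell. Of 21 cholesterol efflux and LXR target genes 5 were higher and 5 lower in males. The desaturases Scd1 (0.997) and Scd2 (0.50) rose, and Apoe, the sterol hydroxylase Cyp27a1 (-0.86) and the phospholipid transfer protein Pltp (-0.67) fell. Of 24 scavenger receptor and lipid-loading genes 3 rose, among them Lrp1 (0.39), and 8 fell, among them the fatty acid binding protein Fabp5 (-0.79) and the lipid droplet protein Plin2 (-0.43).

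Polarisation and NF-kB genes also split in both directions. Of 26 alternative (M2) genes 3 were higher in males, such as the folate receptor Folr2 (0.87), and 9 lower, such as the beta-glucan receptor Clec7a (-1.16) and Pparg (-0.73). Of 22 inflammatory (M1) genes 3 were higher, such as Cd40 (0.79), and 8 lower, such as Cd86 (-1.09), and of 40 NF-kB target genes 9 were higher and 14 lower. None of these 6 lists passed in camera by sex (adjusted p from 0.125 to 0.891). When adjusted over the list alone, the counts higher and lower were 9 and 9 for chemokines, 5 and 5 for LXR targets, 4 and 8 for scavenger receptors, 3 and 10 for M2, 3 and 8 for M1, and 11 and 16 for NF-kB targets. The median (0.01) and mean (-0.02) of the chemokine list differed in sign.

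Other splits of the samples within sex show where chance is unlikely. It is for the genotype count (360, highest of the other splits 16, 1 of 100 as large) and the sex count (5316, highest other 1192, 1 of 100, split within genotype). The real split was also the highest for the agreement of the sexes (0.432, 1 of 100), but the highest other, 0.385, came close. The window around Adam17 held 10 of the 100 smallest p (highest other 5, 1 of 100). Those 10 include Adam17 itself and both probes of Id2, so they are not separate genes. Only 100 splits were drawn, the real one included, so a share under 1 of 100 could not be seen. The female count (4, highest other 1, 1 of 35) was the highest of its splits. However, its calls were the targeted Adam17, both probes of its neighbour Id2, and Slc2a1, so it shows little about genes outside the window. Chance cannot be excluded for the male count of 92, which 2 of 35 splits reached. The other one, with 143, set wild-type males 1, 3 and 4 and ex/ex male 1 against wild-type male 2 and ex/ex males 2, 3 and 4, so it exchanged 1 sample of each genotype. Nor can it be for the 6 lists by genotype (17 of 100 as many, highest other 14). For the interaction count of 0 (limma, 1594 at unadjusted p below 0.05) the splits show nothing, since all 100 reach 0 by definition (highest other 1).

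The calls clustered around Adam17 may reflect DNA of the embryonic stem cell strain that stayed linked to the targeted allele. Within chromosome 12 and without Adam17, 17 of 172 probes of the window passed, against 11 of 545 on the rest (two-sided Fisher's exact test p = 2.49e-05), as such DNA would give. That test counted probes of the same gene as independent. Array probes that mismatch that DNA were argued against for the 5 genes higher in ex/ex, since a mismatch lowers signal. For the genes lower in ex/ex mismatch stays open, because every probe was lower and past the threshold in only 2 of the 4 genes with several probes (Pqlc3 4 of 4, Twistnb 2 of 2, Lpin1 1 of 3, Zfp277 1 of 3). A response of these genes to low Adam17 cannot be told apart from linked DNA here, because every ex/ex sample carries both. The shared sign of all 18 called probes in the 2 sexes does not decide it. Their choice by the effect averaged over the sexes favours a shared sign.

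The sex difference could come from sex itself or from a preparation or array batch that followed it. RNA from other cell types in 1 sex stays open: of the marker lists of 9 other cell types the largest median shift was 0.0255 log2 units in size (B and plasma cells, smallest adjusted p = 0.514, camera), but most of these probes lay near the background of the array, where a median shift excludes nothing. Of the probes past the threshold 3.42% lay on the X or Y chromosome, against 3.72% of those tested, and 4823 were autosomal. Sex and such a batch cannot be told apart, since no label places samples of both sexes in 1 batch.

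A hypothesis that ex/ex macrophages shifted towards the female pattern was also tested. Across genes the log2 fold changes of ex/ex against wild type and of male against female correlated with r = -0.472, but 18 of 100 splits of genotype within sex gave a correlation as low (lowest of the others -0.696), so the test was negative. Without ex/ex male 4 the correlation was -0.343 (lowest of the others -0.615), which leaves open how far that sample alone set it.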
